A study of Mus musculus with 13 samples.

How the data were processed

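The series holds 13 RNA-seq libraries of mouse islet cells sorted by a membrane reporter into GFP-positive beta cells and Tomato-positive non-beta cells. The groups were control beta (n = 4), control non-beta (n = 3), knockout-labelled beta (n = 3) and knockout-labelled non-beta cells (n = 3). Per the labels' protocols, the mice were of the C57BL/6 background and the islets were kept in culture overnight before they were dispersed and sorted. Per the same protocols, libraries came from low-input RNA with SMART-Seq and Nextera chemistry and were read in pairs on a NovaSeq instrument. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR to GRCm38 p6 and tested with edgeR, with no versions given. The strand setting, the counting program, its treatment of reads over several genes and the annotation release are not stated.

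The deposited count table holds raw counts per gene for 55421 genes, per the file headers, and no normalisation was applied by the authors to it. Replicates of a group were similar but not identical (Spearman correlation 0.9727 to 0.9939), and library totals ran from 28.7 to 36.8 M. The authors' deposited tables of pairwise comparisons give log2 fold changes and mean log2 CPM, per the file headers, with the first named group over the second. The same deposited tables give p-values and false discovery rates per gene, by the authors' edgeR run, whose design and filter are not stated. All counts carried a gene identifier, and 54673 identifiers matched the GENCODE annotation with version and 55240 without. The deposited gene lengths equalled the exon union for all 54673 matched genes, and coordinates were taken from the annotation because the deposited start and end equalled the gene span for only 21969.

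Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each comparison only the libraries of its groups entered. Genes were filtered with filterByExpr, scaled by TMM and tested by the quasi-likelihood F test, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The difference of the knockout label between fractions was tested as an interaction contrast over all 13 libraries with 4 group means. Levels are mean CPM ± standard deviation with TMM sizes of all 13 libraries, and the standard error of a log2 fold change was derived from the F statistic. Samples, the tests of these comparisons, the gene lists and most alternatives were chosen before the data were examined. Tests and alternatives added later are named as such where they are given.

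The 35 gene lists held 682 genes, all found in the count table, and Txnrd1 was in none of them. They covered NRF2 targets, the thioredoxin and peroxiredoxin system, the glutathione system, superoxide and hydrogen peroxide removal, NADPH production, selenoproteins, beta-cell identity, insulin granules, disallowed and dedifferentiation genes, the unfolded protein, integrated stress and heat shock responses, p53 targets, ferroptosis and iron, energy metabolism, proliferation, cholesterol synthesis, immune responses, markers of other cell types and sex-linked genes. Lists with at least 5 tested members were tested by limma camera on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. A list was also adjusted alone, as a family of its own members.

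Named genes were set by rule. Txnrd1 came first, then the 10 genes with the largest rise and the 10 with the largest fall in the main comparison, or 5 and 5 in the others. These needed a mean of at least 5 CPM in a group and, for comparisons of groups, every library of a group above every library of the other. For each described list the 4 members with the smallest adjusted p were also taken. Some genes that the rule names are not reported here and were left out of the screen for single libraries. For genes without a count in a group the fold is a lower bound against 3 counts over that group.

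The pipeline was tested on simulated data drawn at the means and spread of these libraries, with 200 changed genes. Apart from these changes a gene had the same mean in all libraries of a comparison. The real differences between fractions were thus absent, and the rates for the interaction and the fractions do not cover genes that differ between them. In the main comparison edgeR recovered 52.2 % of 1.5-fold, 76.1 % of 2-fold and 92.4 % of 4-fold changes with 6.4 % false calls, and no sign was wrong. For the interaction it recovered 25.4 % of 2-fold changes with 3.4 % false calls, against 20.2 % false calls of DESeq2. Between the knockout-labelled fractions it recovered 44.8 % of 2-fold changes with 9.5 % false calls, against 28.3 % of DESeq2. All 4 lists shifted by 0.5 on the log2 scale were recovered by each list test, with no call among the 17 lists in beta cells and the 18 in non-beta cells that held no shifted gene. The genes were drawn independently of each other, so the list tests were not tried on correlated genes. Other groupings of the real beta-cell libraries called up to 18 lists.

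Residuals of libraries with the same replicate number were correlated to check whether the number marks a shared animal or day. The replicate numbers come from the sample titles, and the labels do not say what they mark. In the main comparison the same-number correlations were 0.136, 0.122 and 0.208, each over 0.1, so the numbers were taken to pair the beta-cell libraries, although knockout-labelled replicate 2 went slightly better with control replicate 1 (0.127). The number was used as a block only as an alternative. In a comparison of the genotype labels, a library whose number occurs under a single label then adds nothing to the estimated change. In the control beta group, values of named genes and lists were screened for a library apart from the other 3 by Dixon's ratio, and groups of 3 were not screened. Group labels were also split in all possible ways, or in 100 of the 700 possible ways for the interaction, with every split tested in the same way.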

Results

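Txnrd1 transcripts were higher, not lower, in sorted beta cells labelled knockout. Txnrd1, which encodes the cytosolic thioredoxin reductase, stood at 276.9, 273.6, 293.2 and 323.9 CPM (counts scaled to library size) in the 4 control beta-cell libraries and at 605.7, 599.5 and 540.4 CPM in the 3 knockout-labelled beta-cell libraries. The means were 291.9 ± 23.0 (n = 4) and 581.8 ± 36.1 CPM (n = 3), a 2.00-fold rise (log2 fold change 1.00, standard error 0.08, edgeR adjusted p = 2.22e-05), with every knockout-labelled library above every control library. Txnrd1 did not change in non-beta cells, with 258.7 ± 8.40 CPM in controls and 232.3 ± 17.6 CPM under the knockout label (n = 3 each; log2 fold change −0.14, standard error 0.12, edgeR adjusted p = 0.999). The counts cover the whole gene on chromosome 10 (82833951 to 82897712, + strand, GRCm38), including exons that may remain after recombination, and the deleted exons are not given in the labels. The Txnrd1 count therefore does not check the genotype labels, and the groups are described by label throughout.

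**Figure D1:**
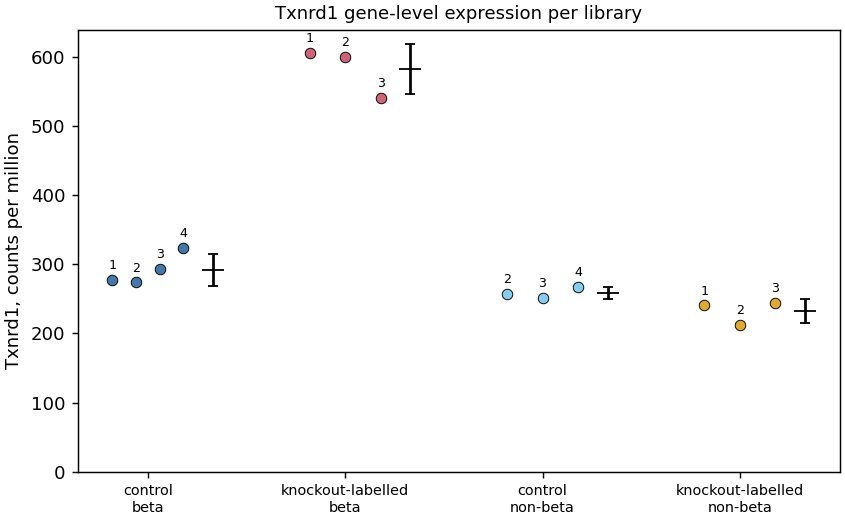
Txnrd1 in CPM in each of the 13 libraries, by sorted fraction and genotype label, with group means and standard deviations as bars. Knockout-labelled beta cells averaged 581.8 CPM against 291.9 CPM in control beta cells, and the non-beta groups lay at 258.7 and 232.3 CPM.

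The sorted fractions differed in their hormone transcripts in all 13 libraries, least so in replicate 3 under the knockout label. Ins2, the main insulin gene, made up 20.179 to 22.598 % of all counts in control beta cells and 21.242, 18.478 and 13.563 % in knockout-labelled beta cells. Gcg, the glucagon gene of alpha cells, made up 15.692 to 19.925 % in the non-beta libraries and 0.03 to 0.068 % in 6 of the beta-cell libraries. Knockout-labelled beta replicate 3 held 0.39 % Gcg, and knockout-labelled non-beta replicate 3 held 2.461 % Ins2 against 0.159 to 0.689 % in the other non-beta libraries, so these carried more RNA of the other fraction. Relative to the mean of the other fraction of the same genotype label, that is 1.87 % for Gcg and 13.09 % for Ins2, against 0.86 to 2.85 % for Ins2 in the other non-beta libraries.

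**Figure D2:**
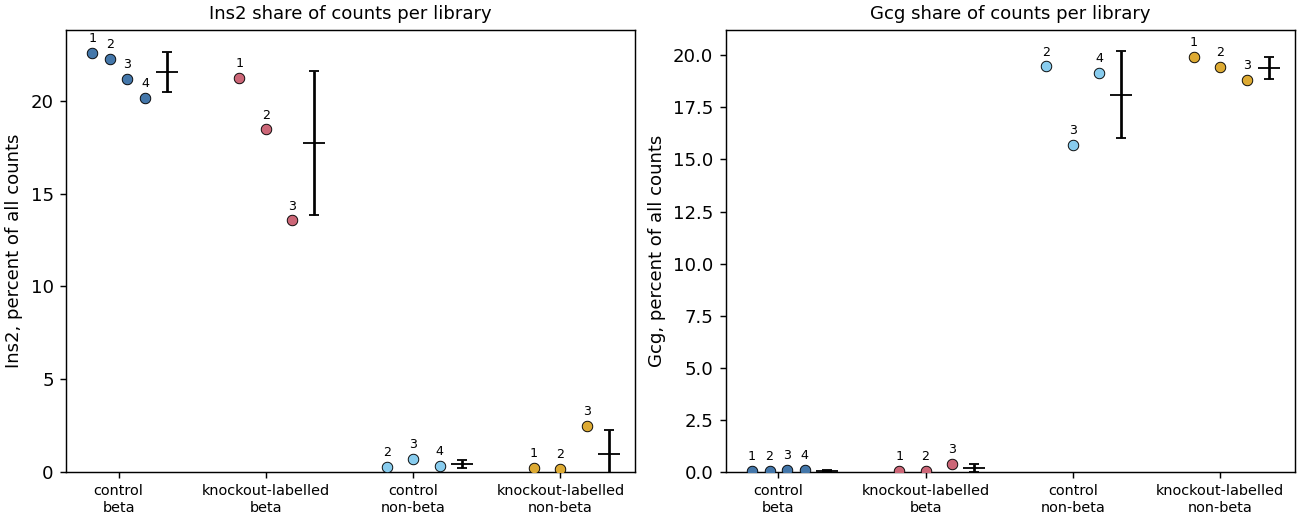
Share of all counts from Ins2 and from Gcg in each library, in percent, by sorted fraction and genotype label. The replicate 3 libraries under the knockout label show the largest share of the other fraction's hormone, 0.39 % Gcg in beta cells and 2.461 % Ins2 in non-beta cells.

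In knockout-labelled beta cells NRF2 target and glutathione genes were higher and genes of beta-cell identity lower. These list results passed camera with its preset correlation, and ended at adjusted p = 0.183, 0.338 and 0.146 with an estimated correlation. Among 17525 genes tested by edgeR, 3525 changed between knockout-labelled and control beta cells, 1778 higher and 1747 lower. Of these, 655 changed at least 2-fold, 340 higher and 315 lower. The heme-degrading enzyme gene Hmox1 rose by 3.14 on the log2 scale (standard error 0.35), from 43.1 ± 17.4 to 380.1 ± 213 CPM. The glucose transporter gene Slc2a2 fell by 2.03 on the log2 scale (standard error 0.15), from 242.2 ± 40.6 to 59.0 ± 10.3 CPM, 4.10-fold lower (edgeR adjusted p = 0.000225 and 1.55e-05; n = 4 control and 3 knockout-labelled libraries).

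The 10 genes with the largest rise had all 3 knockout-labelled libraries above all 4 controls. Ptpn14, a tyrosine phosphatase of Hippo signalling, rose from 0.498 to 6.45 CPM (log2 fold change 3.67, standard error 0.38, edgeR adjusted p = 0.000123). The glutathione S-transferase genes Gstp1 (2.49, 0.13, 160.2 ± 17.8 to 899.5 ± 181 CPM, 4.52e-06), Gstp2 (3.13, 0.27, 4.35e-05) and the pseudogene Gstp-ps (2.53, 0.15, 5.59e-06) rose together, although their similar sequences leave the division of reads among them uncertain. Slc7a11, the cystine importer that feeds glutathione synthesis, rose from 1.78 to 11.01 CPM (2.63, 0.19, 1.56e-05). Slc7a3, a carrier of cationic amino acids, rose from 1.28 to 7.62 CPM (2.58, 0.36, 0.00084). The NRF2-induced iron-binding gene Pir rose from 4.79 to 27.6 CPM (2.52, 0.14, 4.52e-06). Areg, an EGF receptor ligand (2.87, 0.27, 6.57e-05), and Gfra4, a co-receptor of the RET kinase (2.37, 0.26, 0.00019), also rose.

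The 10 genes with the largest fall had all 3 knockout-labelled libraries below all 4 controls. Col6a3, a collagen VI chain, fell from 15.5 to 1.10 CPM (log2 fold change −3.80, standard error 0.24, edgeR adjusted p = 6.48e-06). Fmo1, a flavin monooxygenase, fell from 26.4 ± 2.55 to 2.73 ± 0.211 CPM (−3.27, 0.12, 3.68e-07), 9.62-fold lower. The class I antigen genes H2-Q6 (−2.68, 0.27, 0.000106) and H2-Q7 (−2.28, 0.31, 0.000798), which share sequence, fell with the complement gene Cfb (−2.65, 0.32, 0.000328). Cfb shares 79.5 % of its exon bases with another gene, so its count is uncertain. The adhesion molecule gene Icam1 (−2.63, 0.24, 6.29e-05; 11.7 % shared), the interferon-induced GTPase gene Gbp2 (−2.08, 0.27, 0.000505) and the metalloreductase gene Steap4 (−2.09, 0.36, 0.00285, adjusted p = 0.0547 in a fit of all 13 libraries) also fell. Adam32, a testis-type metalloprotease gene, fell from 16.7 to 3.98 CPM (−2.07, 0.16, 2.11e-05).

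Genes bound by NRF2, the transcription factor of the oxidative stress response, were raised almost throughout. Of 36 tested members, 31 rose and 1 fell (32 and 1 adjusted over the list alone), with a median log2 fold change of 1.07 (camera adjusted p = 5.11e-20, adjusted p = 0.183 with an estimated correlation). The glutathione peroxidase gene Gpx2 went from 74.3 to 293.3 CPM (log2 fold change 1.98, standard error 0.12, edgeR adjusted p = 6.1e-06). Srxn1, which reduces overoxidised peroxiredoxins, went from 190.2 to 591.7 CPM (1.64, 0.12, 1.55e-05), and the epoxide hydrolase gene Ephx1 rose by 1.38 (0.10, 1.18e-05). The glutathione system followed, with 15 of 30 members higher and 1 lower (16 and 2 over the list alone), a median of 0.32 and camera adjusted p = 6.37e-05 (adjusted p = 0.338 with an estimated correlation). Gclc, which sets the rate of glutathione synthesis, rose from 50.2 to 118.7 CPM (1.25, 0.09, 1.56e-05), and the glutathione transferase Gsto1 rose by 1.62 (1.55e-05). Enzymes that remove superoxide and hydrogen peroxide rose in 6 of 12 cases with none lower (6 and 0 over the list alone; median 0.26, camera adjusted p = 0.00194, adjusted p = 0.518 with an estimated correlation). Among them were catalase, Cat (1.71, 0.11, 7.19e-06; 14.3 to 46.7 CPM), Sod1 (0.76, 0.00107) and the phospholipid peroxidase Gpx4 (0.74, 0.00146).

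The thioredoxin and peroxiredoxin system around Txnrd1 did not pass as a list: 6 of 27 members rose and 3 fell, the same over the list alone, with a median of 0.18 (camera adjusted p = 0.0571). It passed upward without control beta replicate 1 or 3 (adjusted p = 0.0434 and 0.0457) and without knockout-labelled beta replicate 2 or 3 (0.0458 and 0.0247). Within it the peroxiredoxin Prdx1 rose by 0.75 on the log2 scale (edgeR adjusted p = 0.00112), the disulfide isomerase Txndc5 fell by 0.37 (0.00276) and the peroxiredoxin-regenerating Sesn1 fell by 0.49 (0.00286). NADPH production moved both ways: 4 of 19 members rose and 2 fell (5 and 3 over the list alone), and the median of −0.01 lay opposite to the mean of 0.09 and to the upward test (camera adjusted p = 0.436). The pentose phosphate genes Pgd (1.11, 0.09, 2.69e-05) and Taldo1 (0.77, 9.73e-05) and the malic enzyme Me1 (0.82, 3.23e-05) rose. G6pdx, the entry enzyme of that pathway, fell from 70.0 to 36.0 CPM (−0.96, 0.08, 2.72e-05; 13.6 % of its exon bases shared). Selenoproteins did not move as a list, with 5 of 20 higher and 2 lower (6 and 3 over the list alone), a median of 0.03 and camera adjusted p = 0.396. The deiodinase Dio1 fell by 0.69 (0.000128) and the selenium carrier Selenop by 0.45 (0.00131; 15.4 % shared).

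Genes of beta-cell identity and function fell as a group in knockout-labelled beta cells. None of 35 tested members rose and 24 fell (0 and 27 over the list alone), with a median log2 fold change of −0.48 (camera adjusted p = 2.4e-12, adjusted p = 0.146 with an estimated correlation). Mafa, the transcription factor of mature beta cells, fell from 359.6 ± 30.4 to 106.4 ± 31.2 CPM (log2 fold change −1.76, standard error 0.16, edgeR adjusted p = 6.29e-05). The maturity peptide Ucn3 fell from 549.3 to 242.6 CPM (−1.18, 0.08, 1.25e-05, adjusted p = 0.333 when all 13 libraries shared a fit). The insulin-folding oxidase Ero1lb fell from 1328 to 607.5 CPM (−1.13, 0.08, 1.55e-05). Insulin granule genes fell in 10 of 25 cases and rose in 1 (11 and 1 over the list alone; median −0.16, camera adjusted p = 0.0012, adjusted p = 0.154 with an estimated correlation). The prohormone convertase Pcsk1 fell from 418.3 to 221.6 CPM (−0.91, 0.000123), the granule-docking Sytl4 fell by 0.88 (0.000231) and the granule zinc carrier Slc30a8 by 0.73 (0.00197). The granule protein Vgf was the 1 riser (1.54, 0.000472; 39.4 to 114.8 CPM). The Pcsk1, Sytl4 and Vgf calls ended at adjusted p = 0.078, 0.437 and 0.0512 in the fit of all 13 libraries.

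The list of 9 genes of dedifferentiated or progenitor-like beta cells passed upward, although only 2 members were called, both higher (the same over the list alone). Its median was 0.66, with camera adjusted p = 0.0295 (adjusted p = 0.25 with an estimated correlation). The growth regulators Myc (0.84, edgeR adjusted p = 0.00137) and Mycl (1.46, 0.00952; 0.293 to 0.815 CPM) were the called members, while the progenitor enzyme Aldh1a3 (1.43, 0.0991) and Cd81, a surface marker of immature beta cells (0.66, 0.0801), did not pass. Both passed without knockout-labelled beta replicate 2 (adjusted p = 0.00499 and 0.0127) and with a replicate block (0.0213 and 0.000683). Without control beta replicate 4 or knockout-labelled beta replicate 3 this list ended at adjusted p = 0.0542 and 0.0649, and with the stricter filter it ended at 0.0905. Mycl ended at 0.0536 without knockout-labelled beta replicate 1. Genes normally silenced in beta cells did not move as a list: 2 of 12 rose and none fell (the same over the list alone; median 0.26, camera adjusted p = 0.273). Of these the chemokine Cxcl12 rose close to the detection limit (1.76, 0.0314), while Smad3 (−0.49, 0.216) and the hexokinase Hk1 (1.38, 0.231) did not pass. The Cxcl12 call ended at adjusted p = 0.0504 to 0.088 on leaving out any library but control beta replicate 1.

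**Figure D3:**
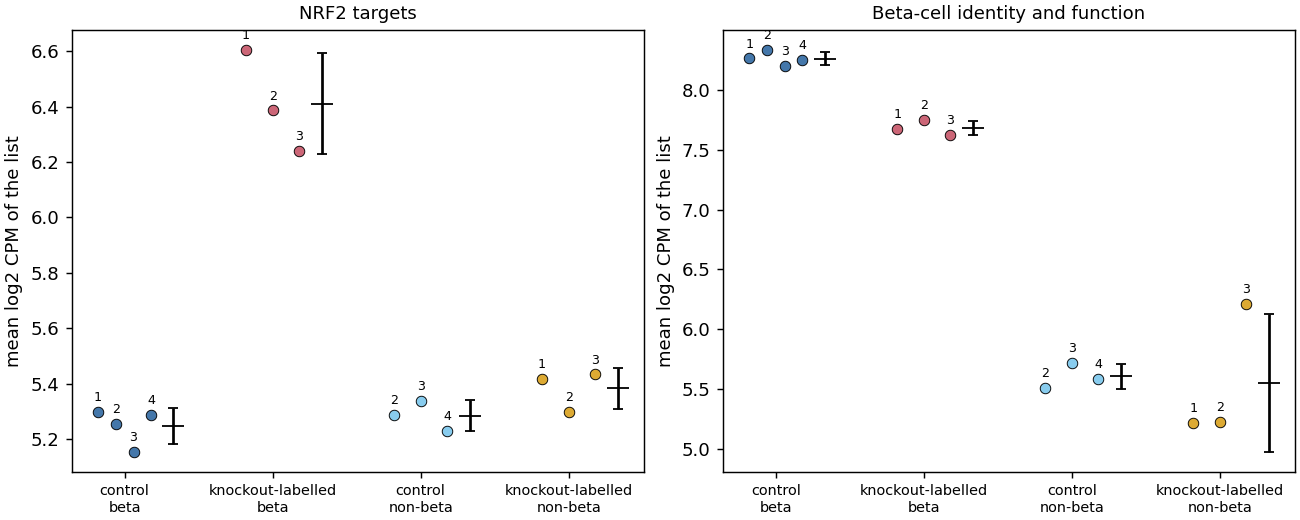
Mean log2 CPM of the members of selected gene lists in each library, by sorted fraction and genotype label. NRF2 targets were higher (median log2 fold change 1.07) and beta-cell identity genes lower (median −0.48) in knockout-labelled than in control beta cells.

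Genes of the unfolded protein response and of the integrated stress response moved in opposite directions. Chaperones and isomerases of the unfolded protein response fell in 13 of 25 cases with none higher (18 and 0 over the list alone; median −0.28, camera adjusted p = 3.28e-06, adjusted p = 0.183 with an estimated correlation). These included the disulfide isomerases Pdia6 (−0.68, standard error 0.07, edgeR adjusted p = 0.000106), Pdia4 (−0.58, 0.000236) and Pdia3 (−0.48, 0.00146) and the chaperone partner Sdf2l1 (−0.88, 0.000307). Targets of the integrated stress response, which slows translation, rose in 21 of 30 cases with none lower (24 and 0 over the list alone; median 0.52, camera adjusted p = 1.54e-11, adjusted p = 0.183 with an estimated correlation). The pseudokinase Trib3 rose from 195.7 to 445.2 CPM (1.19, 0.09, 2.37e-05), the stress hormone Gdf15 by 1.44 (2.39e-05), and Ppp1r15a, which ends the translation block, by 1.05 (4.45e-05).

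Some damage, iron and heat shock genes rose. Targets of p53 rose in 8 of 22 cases and fell in 1 (the same over the list alone; median 0.25, camera adjusted p = 0.00774, adjusted p = 0.299 with an estimated correlation), among them the pro-apoptotic Bbc3 (0.84, edgeR adjusted p = 0.00301), the AKT inhibitor Phlda3 (0.94, 0.00347) and the cell-cycle inhibitor Cdkn1a (0.81, 0.00475; 60.0 to 105.3 CPM). Ferroptosis and iron genes rose in 6 of 18 cases and fell in 1 (8 and 3 over the list alone; median 0.27, camera adjusted p = 0.0327, adjusted p = 0.299 with an estimated correlation). The ferritin chains Ftl1 (1.36, 2.2e-05; 4038 to 10310 CPM, 34.6 % of its exon bases shared) and Fth1 (0.88, 0.000338) rose. Leaving out control beta replicate 2 or knockout-labelled beta replicate 3 ended the ferroptosis call at adjusted p = 0.0619 and 0.0797. Heat shock genes rose in 6 of 18 cases and fell in 2 (10 and 2 over the list alone; median 0.42, camera adjusted p = 0.0048, adjusted p = 0.644 with an estimated correlation). The chaperones Hspb8 (1.79, 0.000121), Hsp90aa1 (0.72, 0.00444) and Hspd1 (0.38, 0.00356) rose and the immunophilin Fkbp4 fell (−0.42, 0.00201).

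Nuclear genes of oxidative phosphorylation rose by a small margin, 12 of 75 with none lower (10 and 0 over the list alone; median 0.24, camera adjusted p = 3.28e-06, adjusted p = 0.694 with an estimated correlation). The complex I genes Ndufv1 (0.36, edgeR adjusted p = 0.00768), Ndufa5 (0.54, 0.0116) and Ndufa8 (0.37, 0.023) and the ATP synthase gene Atp5c1 (0.35, 0.0179) led it. Leaving out control beta replicate 2, knockout-labelled beta replicate 1 or replicate 2 ended the calls of Atp5c1 (adjusted p = 0.058, 0.0728 and 0.053) and Ndufa8 (0.0681, 0.0982 and 0.074), and knockout-labelled beta replicate 1 also that of Ndufa5 (0.0563). With fry, which tests whether the genes of a set move on balance one way and makes no comparison with other genes, oxidative phosphorylation, heat shock and interferon genes did not pass (adjusted p = 0.207, 0.0892 and 0.243). Of lists that camera did not call, fry called NADPH production upward (0.00533) and alpha-cell (0.0148) and leukocyte markers (0.0304) downward.

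Some immune-type genes expressed in beta cells fell. Interferon response genes fell in 6 of 24 cases with none higher (the same over the list alone; median −0.41, camera adjusted p = 0.00285, adjusted p = 0.694 with an estimated correlation). The interferon regulator Irf7 fell from 187 ± 34.7 to 75.5 ± 12.5 CPM (−1.31, standard error 0.15, edgeR adjusted p = 0.000235), the GTPase Gbp3 by 1.78 (0.000999) and the immunoproteasome subunit Psmb8 by 0.48 (0.0228). NF-kappaB and cytokine genes fell in 6 of 15 cases with none higher (8 and 1 over the list alone; median −0.67, camera adjusted p = 0.00774, adjusted p = 0.537 with an estimated correlation). They included the inducible nitric oxide synthase Nos2 (−2.36, 0.00105; 4.65 to 0.901 CPM), the chemokine Cxcl1 (−1.55, 0.0079) and the NF-kappaB inhibitor Nfkbia (−0.67, 0.0174). The interferon call ended without control beta replicate 4 (median −0.22, adjusted p = 0.0542), without knockout-labelled beta replicate 3 (0.0624) and with a replicate block (0.0866). The block also takes control beta replicate 4 out of the label comparison, so it is not a separate check. The NF-kappaB call ended with the stricter filter (median −0.50, adjusted p = 0.0905). Psmb8 ended without control beta replicate 3 (0.058) and without knockout-labelled beta replicate 2 (0.0598).

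The remaining lists did not pass camera in beta cells. Cell-cycle genes (19 tested) and sex-linked genes (5 tested) held no changed member under either adjustment (adjusted p = 0.729 and 0.557), and Kif20a, a mitotic motor, lay at −0.24 (edgeR adjusted p = 0.107). Glycolysis genes split 2 higher and 2 lower of 22 (3 and 3 over the list alone; camera adjusted p = 0.396), with the enolase Eno2 higher (0.48, edgeR adjusted p = 0.00177). Cholesterol synthesis genes fell in 4 of 24 cases (0 higher; the same over the list alone; median −0.12, 0.164). DNA synthesis genes rose in 3 of 14 cases and fell in 1 (the same over the list alone; 0.265), with the sliding clamp Pcna at 0.39 (0.00499) and the replicative helicase Mcm6 at −0.90 (0.0175). Immediate early genes rose in 2 of 20 cases (1 over the list alone; 0.523), Atf3 by 2.16 (0.000885) and Klf4 by 0.86 (0.0429). Mitochondrially encoded mRNAs rose in 4 of 12 cases and fell in 1 (4 and 2 over the list alone; 0.616), with mt-Co2, a cytochrome oxidase subunit, at 0.86 (0.0194), and their median of −0.02 lay opposite to the mean of 0.16 and the upward test. Without knockout-labelled beta replicate 1 the calls of Mcm6, mt-Co2 and Klf4 ended (adjusted p = 0.0721, 0.088 and 0.0817), and Klf4 ended also without control beta replicates 2, 3 and 4 (0.107, 0.0949 and 0.068) and knockout-labelled beta replicate 3 (0.142). Under other settings some of these lists passed: glycolysis upward without control beta replicate 4 (0.0297) and with a replicate block (0.044), cholesterol synthesis downward without knockout-labelled beta replicate 3 (0.000775), and immediate early genes upward without knockout-labelled beta replicate 2 (0.00915).

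Markers of other islet and pancreas cells gave no list call in beta cells. Ductal keratin genes rose, Krt7 from 910.2 to 1505 CPM (0.73, standard error 0.07, edgeR adjusted p = 0.000119), Krt8 by 0.75 (0.0012) and Krt18 by 0.67 (0.00128), in a list with 3 of 11 higher and 1 lower (the same over the list alone; camera adjusted p = 0.306). Alpha-cell markers changed in 1 case upward and 4 downward of 9 (2 and 4 over the list alone; 0.265), the amino acid carrier Slc7a2 by −1.02 (1.55e-05). Delta-cell markers held 1 fall among 6 (2 over the list alone; 0.627), and their median of 0.41 lay opposite to the downward test. Of 4 tested pancreatic polypeptide and epsilon-cell markers 2 rose (3 over the list alone), Ppy by 1.42 (0.0264). Acinar markers (17 tested) held no called member (0.121) at a median of 1.18, with the trypsinogen Prss2 at 2.00 (0.0561). Endothelial markers held 1 rise among 6 (the same over the list alone; median 1.34, 0.242), Pecam1 by 2.25 (0.0436), and leukocyte markers 1 fall among 8 (the same over the list alone; 0.0619), the lysosomal Cd68 by 0.52 (0.017). Stellate (1 tested), glial (3 tested) and erythrocyte markers (0 tested) were too few for camera. Knockout-labelled beta replicate 3 stood above the other beta libraries in mean log2 CPM of acinar (0.405 against −1.868 to −0.898) and endothelial markers (1.628 against −1.698 to 0.196). The acinar list passed upward without control beta replicate 3 (adjusted p = 0.0285), without knockout-labelled beta replicate 1 or 2 (0.00233 and 0.0106) and with a replicate block (0.00355), and Prss2 without knockout-labelled beta replicate 1 or 2 (0.0243 and 0.0347) and with the block (0.0309). The leukocyte list passed downward without knockout-labelled beta replicate 3 (0.00292) and with the block (0.0242). The Ppy call ended with DESeq2 (adjusted p = 0.0608). Leaving out 1 library ended the call of Ppy (control beta replicates 1 and 4, adjusted p = 0.0532 and 0.0586, knockout-labelled beta replicate 3, 0.0992) and of Cd68 (knockout-labelled beta replicate 2, 0.06). It also ended that of Pecam1 (control beta replicates 1, 2 and 4, 0.0966, 0.115 and 0.0815, knockout-labelled beta replicates 2 and 3, 0.0604 and 0.236).

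**Figure D4:**
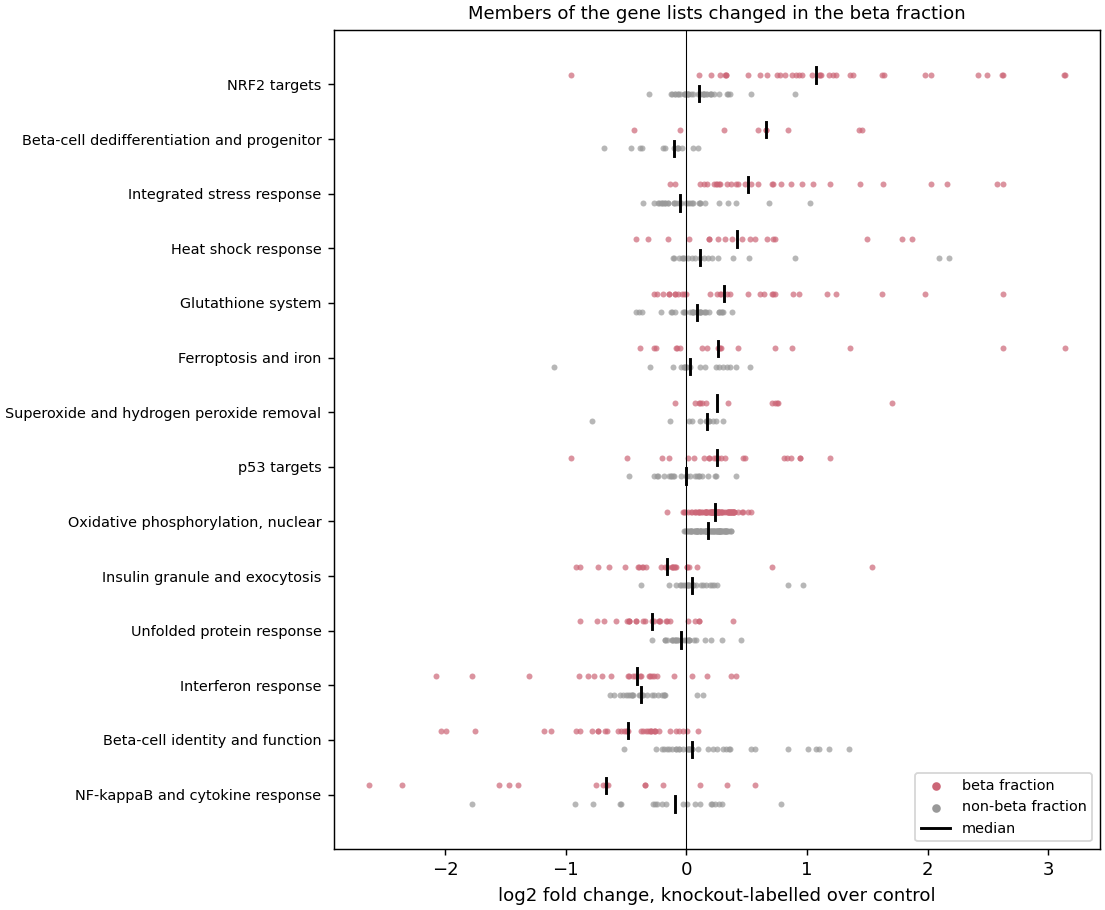
Log2 fold change, knockout-labelled over control, of the members of selected gene lists, drawn separately for the beta and the non-beta fraction. Each point is 1 gene in a fraction and each line the list median in that fraction. Medians in the beta fraction ran from 1.07 for NRF2 targets to −0.67 for NF-kappaB genes.

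In the authors' deposited table for these groups, 3051 of 11810 listed genes had a false discovery rate below 0.05, 1578 higher and 1473 lower. Of these, 2695 were also called here, all with the same sign. Besides the calls named above, the fit of all 13 libraries ended those of Cxcl12 (adjusted p = 0.0749), Mycl (0.133), Bbc3 (0.0709), Klf4 (0.11), Ndufa8 (0.0738), mt-Co2 (0.123), Psmb8 (0.0646) and Nfkbia (0.066). The labels do not state how many mice a library pools or whether replicates share mice, so every p measures the spread between these samples. No list call in either comparison of the genotype labels or between the fractions passed with an estimated correlation, whereas the NRF2 and granule calls of the contrast between fractions did.

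In non-beta cells, which are not meant to express the Cre, the number of changed genes depended on the test. edgeR called 0 of 18908 genes (lowest adjusted p = 0.23), although 821 had a raw p below 0.05. DESeq2 called 24, limma voom 14 and edgeR with a replicate block 12. The block leaves the label comparison to replicates 2 and 3, the only numbers held by both labels. Tdg, a DNA glycosylase of demethylation, had the lowest p (log2 fold change −1.68, edgeR adjusted p = 0.23). Of the other genes called by the authors, none passed the main edgeR test here. Examples were the Ras-related growth inhibitor Rerg (−1.63, 0.394), the endothelial and progenitor marker Cd34 (−0.85, 0.507) and the lysozyme gene Lyz2 (0.73, 0.507). The authors' deposited table gave 12 of 12853 listed genes a false discovery rate below 0.05, 5 higher and 7 lower, among them Tdg (3.91e-08), Rerg (0.00044), Nupr1 (1.03, 0.00514), Cd34 (0.0094) and Lyz2 (0.0432). On simulated data with these sample sizes edgeR recovered 25.4 % of 2-fold and 87.9 % of 4-fold changes, so smaller effects can be missed.

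Camera called 8 lists in non-beta cells, and none passed with an estimated correlation or with fry. Mitochondrially encoded mRNAs were higher (median log2 fold change 0.85, camera adjusted p = 1.13e-09, adjusted p = 0.744 with an estimated correlation; 10 of 12 higher over the list alone), as were nuclear oxidative phosphorylation genes (0.18, 1.13e-09, adjusted p = 0.808 with an estimated correlation; 0 of 75 over the list alone). Endothelial markers were lower (−0.44, 2.43e-07, adjusted p = 0.744 with an estimated correlation; 4 of 14 lower over the list alone), including the VEGF receptor Kdr at −0.82. Leukocyte markers were higher (0.12, 0.00011, adjusted p = 0.574 with an estimated correlation; 3 of 16 over the list alone), with the signalling adaptor Tyrobp at 0.78 (edgeR adjusted p = 0.88). Heat shock genes (0.11, 0.0222, adjusted p = 0.808 with an estimated correlation; 1 of 19 over the list alone) and selenoproteins (0.10, 0.0393, adjusted p = 0.808 with an estimated correlation; 0 of 20) were higher. Cell-cycle genes (−0.24, 0.0251, adjusted p = 0.808 with an estimated correlation; 0 of 18) and interferon genes (−0.38, 0.0309, adjusted p = 0.929 with an estimated correlation; 0 of 24) were lower. The interferon direction rested on control replicate 4: without it the median was 0.12 with an upward test (adjusted p = 0.473), and without knockout-labelled replicate 3 the call ended too (−0.16, 0.942). Cell-cycle genes ended without the same libraries (0.04, 0.64 and −0.15, 0.285). Selenoprotein and heat shock calls ended without control replicate 2 (0.0805 each), control replicate 4 (0.517 and 0.0951), knockout-labelled replicate 1 (0.177 and 0.158) or knockout-labelled replicate 3 (0.153 and 0.268). NRF2 targets did not pass (0.10, adjusted p = 0.0612; 0 of 36 by either adjustment), nor did NF-kappaB genes (−0.09, 0.464; 0 of 20). Identity genes had a median of 0.05 against a downward test (0.919; 0 of 35), and integrated stress genes −0.05 against an upward test (0.884; 1 of 30 over the list alone). Of these lists, leaving out 1 library made NRF2 targets pass upward (control replicate 3, adjusted p = 0.0304, knockout-labelled replicate 2, 0.0124), as did the stricter filter (0.0173). It made identity genes (knockout-labelled replicate 3, 0.00171), NF-kappaB genes (control replicate 2, 0.0118) and integrated stress genes (control replicate 3, 0.00773) pass downward.

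Control beta cells differed from control non-beta cells in 10163 of 19014 genes, 4723 higher and 5440 lower. Mafa, the factor of mature beta cells, stood at 359.6 ± 30.4 CPM (n = 4) against 3.27 ± 1.46 CPM (n = 3; log2 fold change 6.78, standard error 0.28, edgeR adjusted p = 8.87e-08). The mesothelin-like Mslnl (7.49, 0.61, 5.63e-06), the carbonic anhydrase relative Car10 (7.13, 0.25, 4.78e-08; 44.3 against 0.314 CPM), the mesothelin gene Msln (6.89, 0.50, 2.59e-06) and the calcium-binding Cib3 (6.71, 0.38, 5.9e-07) rose furthest. The genes with the largest fall had no count in control beta cells, so only lower bounds against a floor of 3 counts over the group are given, which cover counting error alone. The immunoglobulin receptor Fcgrt was at least 628-fold lower (15.3 ± 4.19 CPM in non-beta cells, edgeR adjusted p = 4.14e-06), the endothelial factor Nkx2-3 at least 533-fold (4.19e-06) and the microglial-type marker Tmem119 at least 477-fold (1.13e-06). The macrophage receptor Cx3cr1 was at least 451-fold (6.5e-05) and the potassium channel Kcnk5 at least 430-fold lower (0.000114). Identity genes were higher in 28 of 35 cases and lower in 4 (29 and 4 over the list alone; median 2.45, camera adjusted p = 7.77e-11, adjusted p = 0.0724 with an estimated correlation). Alpha-cell markers were lower in 14 of 15 cases and higher in 1 (the same over the list alone; camera adjusted p = 1.81e-06, adjusted p = 0.0661 with an estimated correlation), Gcg by 8.34 on the log2 scale. The authors' deposited table gave 6010 of 11735 listed genes a false discovery rate below 0.05, and 5708 of these were called here with the same sign.

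The contrast of fractions under the knockout label called 7992 of 18775 genes, 3577 higher in beta cells and 4415 lower. Mafa remained beta-specific at a lower level, 106.4 against 2.25 CPM (log2 fold change 5.51, standard error 0.39, edgeR adjusted p = 3.33e-05; n = 3 each). Mslnl (5.96, 0.73, 0.000338), Car10 (5.23, 0.66, 0.000402), the metal-transport mediator Cnnm1 (5.04, 0.57, 0.000218) and the neuronal receptor Lingo3 (4.75, 0.50, 0.000157) stood highest. The matrix gene Postn (at least 519-fold, edgeR adjusted p = 7.32e-05), the lymphocyte homing receptor Ccr7 (at least 463-fold, 5.89e-05) and the co-stimulator Cd86 (at least 188-fold, 0.000117) had no count in knockout-labelled beta cells. Clps, the acinar colipase, was 0.506 against 396.6 CPM (−9.62, 0.74, 4.26e-05), and the microRNA gene Mir6969 lay at −9.95 (1.04, 0.00015). NRF2 targets were higher in beta cells in 27 of 37 cases and lower in 4 (29 and 5 over the list alone; median 0.84, camera adjusted p = 1.13e-06, adjusted p = 0.365 with an estimated correlation), whereas in controls they were balanced (10 higher and 11 lower of 36, the same over the list alone; median 0.01, 0.766). The authors' deposited table gave 4745 of 11583 listed genes a false discovery rate below 0.05, and 4179 of these were called here with the same sign.

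The effect of the knockout label differed between fractions for 185 of 19942 genes, 122 with a higher and 63 with a lower contrast in beta cells. Ptpn14 (contrast 3.81, standard error 0.57, edgeR adjusted p = 0.00927), the thrombin receptor F2r (3.42, 0.37, 0.0015), the glucuronosyltransferase Ugt2b35 (3.50, 0.0131), the receptor adaptor Sh2b2 (3.10, 0.00761) and the actin-associated Filip1l (3.01, 0.0361) led the higher genes. Col6a3 (−3.57, 0.58, 0.0131), Fmo1 (−2.38, 0.0188), the hair-cell cadherin Pcdh15 (−2.28, 0.0131), the immune transcript AW112010 (−2.14, 0.0311) and Icam1 (−2.09, 0.0303) led the lower genes. Txnrd1 itself had a contrast of 1.15 (0.13, 0.00208). Leaving out 1 library ended the Fmo1 call (control non-beta replicate 2, adjusted p = 0.0619, knockout-labelled beta replicate 1, 0.0563, knockout-labelled non-beta replicate 3, 0.0564). It ended the Filip1l call at 0.0545 to 0.102 for all but control beta replicate 1, control non-beta replicate 3 and knockout-labelled beta replicate 1. It ended the AW112010 call at 0.0508 to 0.105 for all but control non-beta replicates 3 and 4, knockout-labelled beta replicate 2 and knockout-labelled non-beta replicate 3. The Icam1 call ended at 0.0535 to 0.103 without control beta replicate 1, control non-beta replicate 2, any knockout-labelled beta library, or knockout-labelled non-beta replicates 1 and 2. With the replicate number within each genotype as a block 50 genes were called, and the calls of Sh2b2 (0.0549), Pcdh15 (0.0558), Filip1l (0.149), Fmo1 (0.0739), AW112010 (0.0567) and Icam1 (0.056) ended. Of the 185 genes 181 were tested in beta cells alone, 179 changed there and 178 of those had the same sign. The NRF2 contrast had a median of 0.90 (16 higher and 1 lower of 37; 26 and 1 over the list alone; camera adjusted p = 1.56e-22, adjusted p = 0.0202 with an estimated correlation). The granule contrast had a median of −0.23 (0 higher and 1 lower of 26, the same over the list alone; 0.000169, adjusted p = 0.0202 with an estimated correlation). Its medians were −0.16 in beta and 0.05 in non-beta cells. Knockout-labelled non-beta replicate 3, with Ins2 at 13.09 % of the beta-cell level, can add to the non-beta value. The contrast was not tested without that library.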

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

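The 4 tests on Txnrd1, the test of admixture on the identity genes, both tests of an islet-wide difference and both tests of the later-numbered control library on the immune lists, and the number of drawn splits of the interaction, were chosen only after those results were seen, and the other tests were chosen before. The later-numbered libraries are replicate 4 of control beta and of control non-beta cells, whose library numbers lie far above all others. No knockout-labelled library has such a number, and whether these libraries were prepared apart is not stated.

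Txnrd1 counts were higher, not lower, in beta cells labelled knockout. A swap of 1 library between the genotype labels is argued against, because the lowest knockout-labelled library held 1.67 times the Txnrd1 level of the highest control. Reads of an overlapping gene are argued against too, because 0 % of the Txnrd1 exon bases lie under exons of another gene. A rise together with the NRF2 response is possible, since 47.2 % of the tested NRF2 list members had a lower fold change than Txnrd1, so that it lay near the middle of that list. An exchange of the labels as a whole stays open: control-labelled beta cells held 1.19 times the Txnrd1 level of all non-beta libraries, and the deleted exons are not given.

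Beta-cell identity genes were lower under the knockout label. Admixture of non-beta cells is argued against, because the highest Gcg level in a knockout-labelled beta library was 1.87 % of the knockout-labelled non-beta mean. Hormone transcripts setting the scale are argued against, because the list median without the 7 hormone genes was −0.496. The single library with the most non-beta RNA is argued against, because the median without knockout-labelled beta replicate 3 was −0.466. Whether the fall reflects loss of maturity or a general response to stress stays open.

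The interferon and NF-kappaB lists were lower under the knockout label, with 12 called members between them. Leukocyte RNA in the control libraries is argued against with all libraries in the test. At the share of 15 leukocyte markers it accounted for a median of −0.41 % of the fall of the 12 called members, at most −0.06 %. The median marker level was 0.82 % in control and 0.99 % in knockout-labelled beta cells, each of the non-beta level of the same label. Knockout-labelled beta replicate 3 stood highest in mean log2 CPM of these markers (0.78, replicates 1 and 2 −1.227 and −0.8, controls −0.665 to −0.162). Without it the leukocyte list passed downward (camera adjusted p = 0.00292). The share was not computed without that library, so the point stays open for the others. The later-numbered control library is argued against for the NF-kappaB list, whose median kept 0.8 of its size without it (−0.668 to −0.532) and whose call stayed (adjusted p = 0.019). For the interferon list it stays open, since the median kept 0.54 (−0.408 to −0.221) and the call ended (0.0542). An islet-wide difference between the animals stays open for NF-kappaB genes (camera p = 0.262 in non-beta cells, contrast between fractions at adjusted p = 0.67 with an estimated correlation) and for interferon genes, which were lower in non-beta cells (camera p = 0.00635, adjusted p = 0.929 with an estimated correlation) by the weight of control non-beta replicate 4 (without it median 0.122, adjusted p = 0.473).

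The effect of the knockout label differed between the fractions for 29 of 133 named genes, in edgeR log2 contrast of beta over non-beta cells. Among all tested genes it was 185 of 19942. The named genes were chosen largely by their change in the same beta-cell libraries, so a high share was built in and no conclusion is drawn from it. Higher in beta cells were Txnrd1 1.15, Ptpn14 3.81, Hmox1 2.82, Gstp2 2.6, Slc7a11 2.53, Slc7a3 2.94, Gstp-ps 2.36, Pir 2.72, Gstp1 2.31, Gfra4 2.34, Gpx2 2.09, Ephx1 1.18, Srxn1 1.7, Gsto1 1.33, Gclc 1.37, Cat 1.85, Me1 0.9, Taldo1 0.77, Gdf15 1.66, Ftl1 1.09 and Hspb8 1.82. Lower were Col6a3 −3.57, Fmo1 −2.38, H2-Q6 −2, Icam1 −2.09, G6pdx −0.86, Ero1lb −1.06, Slc30a8 −0.97 and Slc7a2 −1.1.

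By camera 14 lists also differed, with the median contrast and the adjusted p with an estimated correlation as follows. Positive medians were those of NRF2 targets 0.9 (0.0202), glutathione 0.32 (0.297), superoxide and hydrogen peroxide removal 0.17 (0.67), disallowed genes 0.61 (0.67), dedifferentiation 0.8 (0.324), integrated stress 0.53 (0.387), p53 targets 0.26 (0.387) and ferroptosis and iron 0.29 (0.387). Negative medians were those of identity −0.64 (0.0694), granule −0.23 (0.0202), unfolded protein −0.25 (0.297), mitochondrially encoded −0.8 (0.566), cholesterol −0.24 (0.751) and NF-kappaB genes −0.56 (0.67). These list contrasts were not tested with libraries left out.

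Of 177 values screened in the 4 control beta libraries, 14 had a library apart from the other 3, and about 1 in 20 would be apart without cause. Control beta replicate 4 was apart for Hmox1 at 69.1 CPM (others 32.9 to 37.5), Cdkn1a at 78 (52.9 to 54.8), Hsp90aa1 at 307 (245 in the others), mt-Co3 at 4.82 (9.35 to 9.81), Srebf2 at 159 (141 to 143) and Ccnb2 at 1.72 (0.422 to 0.61). It was also apart for the mitochondrial share of counts at 0.228 % (0.276 to 0.285) and for the mean log2 CPM of p53 targets at 3.56 (3.18 to 3.2), mitochondrially encoded mRNAs at 5.02 (5.57 to 5.61) and interferon genes at 5.06 (4.04 to 4.21). Replicate 1 was apart for Dio1 at 189 CPM (166 to 169). Replicate 2 was apart for Cd81 at 90.1 CPM (153 to 161), and replicate 3 for Tm7sf2 at 33.5 (31 to 31.4) and Sparc at 1.65 (0.262 to 0.357).

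The same tests were run with the libraries split in other ways. For beta cells, 1 of 35 splits called as many genes, the real one with 3525 (2.9 %, highest other 2). Of the 8 splits that part every pair of equal number the others called 0 genes. The real split stood far above the others, but 2.9 % is the lowest share that 35 splits can give, so chance is not excluded. The other splits also mix the labels, which widens the spread within their groups. The splits that part every pair are too few for a share of their own. For control fractions it was 1 of 35 (10163, highest other 0). Every other split there mixes beta and non-beta cells, so low counts were fixed in advance and no conclusion is drawn. For the knockout-labelled fractions it was 1 of 10 (7992, highest other 0), where the same holds and the splits are too few. For non-beta cells all 10 of 10 splits called as many as the real 0 (highest other 330, which points to a structure of the samples), and 7 of 10 as many lists (real 8, highest other 14), and the splits are too few. For the interaction, where the draws were raised to 100 after the result of fewer draws was seen, 4 of 100 drawn splits called as many genes (4 %, real 185). All 4 kept the real beta-cell labels, and the highest with other beta-cell labels was 159. Those of the 4 with changed non-beta labels called 249, 1053 and 1695, each more than the real split. The count thus follows the beta-cell labels and does not by itself show that the effect differs between fractions. For lists in beta cells 8 of 35 did (22.9 %; real 14, highest other 18, or 12 among the splits that part every pair), so chance cannot be excluded for the count of lists.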

How the results depend on the processing

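The alternatives without both knockout replicate 3 libraries, without genes with shared exons, for list medians in both fractions and for named genes outside the main comparison, and the look at Xist and Ddx3y were chosen only after the result was seen, and the others before. No call of the comparisons had the opposite sign among the calls of another setting. Of the lists called in either fraction, the direction of the list test turned for interferon genes in non-beta cells only, without control non-beta replicate 4 (median −0.633 to 0.122 on leaving out libraries, lowest without knockout-labelled non-beta replicate 1).

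The 3525 genes changed in beta cells became 1673 in a fit of all 13 libraries, of which 1636 were among the first set, and 655 with a log2 fold change of at least 1. The all-library fit takes the wider spread of non-beta cells into the beta-cell test. Leaving out libraries in turn gave 1991 to 4117 genes. Control beta replicate 2 (2218), knockout-labelled beta replicate 1 (1991) and knockout-labelled beta replicate 2 (2343) moved the count by more than 1.5 times; the cause was not tested. The count stayed at 3385 without genes with shared exons and at 4117 without knockout-labelled beta replicate 3. Txnrd1 stayed between 0.966 and 1.051 on the log2 scale. Of 136 named genes, 24 lost their call in the all-library fit and 23 without knockout-labelled beta replicate 1.

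In non-beta cells the 0 calls became 1 without a filter, 24 with DESeq2, 14 with limma voom and 3 in the fit of all 13 libraries; the cause was not tested. Leaving out libraries gave 0 throughout. Between control fractions 10163 genes became 5108 with a log2 fold change of at least 1 (8716 to 10880 on leaving out libraries). Between knockout-labelled fractions 7992 became 4510 with that threshold and 5319 with the stricter filter, which tests fewer genes (6277 to 8752 on leaving out libraries; 8824 without both replicate 3 libraries).

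The 185 genes of the interaction became 543 with DESeq2, 1284 with limma voom and 90 without both later-numbered control libraries; the cause was not tested. Leaving out libraries gave 62 to 289: control beta replicate 1 gave 101, replicate 2 gave 84 and replicate 3 gave 102. Control non-beta replicate 2 gave 62 and replicate 3 gave 289. Knockout-labelled beta replicate 1 gave 80 and replicate 2 gave 110, and knockout-labelled non-beta replicate 1 gave 119 and replicate 2 gave 111. Without both knockout replicate 3 libraries 154 were called, 113 of them among the 185.

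With the replicate number as a block, beta cells had 3544 changed genes, non-beta cells 12, the control fractions 9494, the knockout-labelled fractions 7877 and the interaction 161, or 50 with the block nested in genotype, which takes the number as an animal; whether it is one is not stated. In beta cells, where the numbers were taken to pair the libraries, 16 lists were called, 13 of them among the first 14. The block ended the calls of the interferon list (adjusted p = 0.0866), Srebf2 (0.0615) and mt-Atp8 (0.0902) and of no other named gene or list called in beta cells. It added the lists of glycolysis (0.044), acinar (0.00355) and leukocyte genes (0.0242) and the genes Cd81 (0.000683), Aldh1a3 (0.0213), Fosb (0.0259), Pyy (0.0289), Prss2 (0.0309), Try5 (0.0379), Cd79a (0.0177), C1qa (0.0205), Uty (0.0447) and Ddx3y (0.0342). Elsewhere the correlations were not over 0.1 in each pair, but Ddx3y went with the number: beta and non-beta libraries held 13.05 and 12.5, 20.39 and 21.05, and 10.86 and 8.99 CPM in control replicates 2, 3 and 4, and 12.04 and 11.14, 10.43 and 7.4, and 16.53 and 19.78 CPM in knockout-labelled replicates 1, 2 and 3. The X-linked Xist did not go with the number throughout. It stood at 27.16 and 51.84 CPM in beta and non-beta cells of control replicate 4, and at 29.6 and 55.34 CPM in knockout-labelled replicate 2. Whether fractions of a number share mice stays open. For the interaction the block ended the calls of Icam1 (0.0553) and Filip1l (0.0843), and the nested block also those of Sh2b2, Pcdh15, AW112010 and Fmo1. In non-beta cells 5 lists were called, 3 of them among the first 8, and the calls of nuclear oxidative phosphorylation (0.227), selenoproteins (0.901), heat shock (0.406), cell-cycle (0.227) and interferon genes (0.604) ended, while glycolysis (0.0391) and delta-cell genes (0.0123) were added. Same-number correlations were 0.048 to 0.193 between control fractions, where control non-beta replicate 3 went best with another number (0.12), and 0.084 to 0.093 between knockout-labelled fractions, where each library went best with its own. In the 2 non-beta pairs they were −0.06 and 0.263.

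The 14 lists called in beta cells became 0 with an estimated correlation (13 to 17 on leaving out libraries). The 8 lists in non-beta cells became 0 with an estimated correlation and 0 with fry. Leaving out libraries gave 6 to 14 there, with 13 without control non-beta replicate 3 and 14 without knockout-labelled non-beta replicate 2; the cause was not tested. In the 14 lists the estimated correlation ran from −0.005 to 0.745, at or below 0 for granule and dedifferentiation genes. With an estimate camera also uses the few residual degrees of freedom, which widens the test for every list.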

Other observations

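The value of Pdx1 and the look at Xist and Ddx3y were chosen only after the result was seen, and the other tests before. Genes enriched in beta cells, a set far larger than the identity list, fell as a class under the knockout label. Identity genes were not taken out of the set. With the control libraries split so that enrichment and change were measured in different libraries, 1703 beta-enriched genes had a median log2 fold change of −0.264 and 73.2 % lay below 0 (camera p = 1.16e-11; p = 0.033 with an estimated correlation). Of these genes 396 fell and 79 rose, and the median was −0.278 without knockout-labelled beta replicate 3. The 1510 genes enriched in non-beta cells had a median of 0.239, with 180 higher and 45 lower (camera p = 4.45e-06; p = 0.15 with an estimated correlation), and 0.169 without that library. The controls in the change were control beta replicates 1 and 2, with the lowest Gcg shares of the beta libraries (0.03 and 0.04 %). This can favour a rise of non-beta genes, and the reverse split was not run. Pdx1, the factor that sets the beta-cell lineage, took part in the fall, from 138.5 to 93.5 CPM (−0.56, edgeR adjusted p = 0.000707).

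Genes that changed in knockout-labelled beta cells leaned the same way in non-beta cells, far more weakly. The 1733 genes that rose in beta cells by a median of 0.487 had a median of 0.065 in non-beta cells, with 65.4 % of the same sign (camera p = 6.16e-05; p = 0.0163 with an estimated correlation). The 1677 genes that fell by 0.489 had a median of −0.084, with 68.5 % of the same sign (camera p = 1.7e-05, or 0.0431 with an estimated correlation). Whether the fractions share mice is not stated. If they do, the comparisons are not independent, and these p-values do not allow for that. Beta-cell RNA in the non-beta libraries could account for the rise. The 119 risen genes at least 4 times as high in non-beta as in beta cells had a median of −0.101 there, opposite in sign to the whole set. Among the 1677 fallen genes 23 were of this kind, with a median of −0.325. Beta-cell RNA is argued against for those 23 only and stays open for the other fallen genes. Control replicate 4 stood highest in mean log2 CPM of interferon genes in both fractions (5.057 in beta and 5.519 in non-beta cells). The median of the 23 genes was not computed without these libraries, so their part in it stays open.

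The sorted fractions kept most of their differences under the knockout label, in libraries not shared between the comparisons. Of 18394 genes tested in both, 2936 were higher in beta cells in both genotypes, against 889 by chance, and 3812 were lower in both, against 1222 by chance. Among control libraries cholesterol synthesis genes were higher in beta cells in 20 of 24 cases (median 0.73, camera adjusted p = 1.27e-06, adjusted p = 0.31 with an estimated correlation). Unfolded protein response genes were higher in 21 of 25 (0.94, 2.06e-07, adjusted p = 0.109 with an estimated correlation), and immediate early genes were lower in 20 of 22 (−2.29, 1.02e-06, adjusted p = 0.176 with an estimated correlation).

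Non-beta libraries varied in their exocrine content and interferon genes. The trypsinogen Prss2 stood at 380.9, 427.6 and 1015 CPM in control replicates 2, 3 and 4 and at 1271, 919.1 and 258.5 CPM in knockout-labelled replicates 1, 2 and 3. The interferon-induced chemokine Cxcl10 followed, at 3.202, 4.053 and 29.37 CPM and at 8.992, 9.258 and 3.069 CPM. The split of control replicates 2 and 3 with knockout-labelled replicate 3 against the rest called 330 genes, 59 higher and 271 lower, against 3 in the next split. These groups came from the data, so no test between them is given.

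Xist, the RNA of the inactive X chromosome, was present in all 13 libraries at 18.87 to 55.34 CPM, together with the Y-linked Ddx3y at 7.4 to 21.05 CPM. Each library therefore held RNA of female and of male cells and so of more than 1 mouse. The sex and number of the mice in a library are not given in the labels. Neither Xist (0.03, edgeR adjusted p = 0.918) nor the sex-linked list (camera adjusted p = 0.557) differed between the genotype labels in beta cells, although Ddx3y was lower with a replicate block (−0.38, edgeR adjusted p = 0.0342).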
